A study of Homo sapiens with 2 samples.

How the data were processed

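RNA from cultures of the human esophageal squamous carcinoma line KYSE410 was measured on 2 one-colour (Cy3) expression arrays, 1 for the control and 1 for cells given 50 ng/mL CCL22. Each array carried 62976 spots and 58201 different gene probes of 60 bases. Per the labels' protocols, the cells grew in RPMI medium with 10% serum, and Cy3-labelled cRNA was made from 0.5 ug of RNA. The spots were scanned and extracted with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. Per the file headers, the software subtracted background, detrended the signal over the array, put a surrogate value on spots not above background and marked outlier spots. The deposited scanner files hold intensity values on a linear scale, not normalized between arrays, with the software's error of each spot. Both arrays lay on the same slide and were scanned together, so slide and scan do not separate the groups.

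A second deposited table holds the authors' log2 intensity values, 1 column per array. Its columns had the same sorted values (largest difference 0.000587) and the same median, 3.56, so it was quantile normalized. Each column followed the log2 processed signal of its array with r = 0.9998 for the control and 0.9996 for CCL22 across probes. How its authors made it is not given in the sources used here. It served as an alternative.

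The processed signal was checked against the other columns of the same file before use. Feature Extraction's processed signal is the background-subtracted signal divided by the detrending factor, or the surrogate where one was used. With a tolerance of 0.001 on the log2 scale, this held for 62972 of the 62976 control spots and for 62921 of the 62976 CCL22 spots. It failed at 55 spots of 37 probes on the CCL22 array and at 4 spots on the control array, and those 4 probes were among the 37. The probes belong to 32 genes. The MMP3 spots among them, marked well above background in the files although a surrogate was used, were counted as not above background. For those probes the deposited value is not the quantity that the column holds elsewhere, and they were left out of every comparison unless stated. This step was chosen after seeing the data and departs from the design written beforehand, which assumed that the column could be used throughout. Values with the probes as deposited, and with their signal recomputed from the other columns, are given as alternatives. Background subtraction itself agreed at every spot of both arrays, so the recomputed values rest on pixel means that match the rest of the file. A change carried through all columns of a spot would not be seen by this check.

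Spots of one probe were averaged on the log2 scale after outlier spots were left out (64 gene spots on the control array and 67 on the CCL22 array). No spot was saturated. Each array was scaled by subtracting the 75th percentile of its log2 processed signal, which was 216 for the control and 277 for CCL22 on the linear scale. Gene symbols were updated through the transcript accession of each probe with a RefSeq table of assembly GRCh38.p14, used for names only. This matched 31104 probes. In all, 34051 probes had a gene symbol, for 22906 genes, and 24150 probes had only a locus or transcript identifier. Probe coordinates are those of the files, on hg19 (GRCh37), counted from 1. Exon and UTR annotation of that build was not used here.

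A gene was measured when a probe was well above background on both arrays, and a gene with several such probes took the one with the highest mean signal. The log2 ratio is CCL22 minus control. With 1 array per group no test is possible and no p-value is given. Genes at a fold of 2 or more are counted. The median log2 ratio of each of 39 gene lists, fixed before the data were examined, was set against 10000 random lists of the same size matched on mean signal in 20 bins. The resulting percentile describes these arrays and is no p-value, and lists with fewer than 5 measured genes have none. A gene above background on 1 array only has a lower bound on its fold: its signal against the higher of its own signal on the other array and the lowest signal well above background there. Genes with a left-out probe have no such bound.

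Genes named in the text follow a rule set beforehand. It takes CCR4, CCL22, CCL17, PTK2, DGKA and NOX4 always. It adds the 12 largest and the 12 smallest log2 ratios among genes at or above the 25th percentile of mean signal whose probes share a sign, and up to 4 members of each list by size of the log2 ratio. It also takes the 5 genes each way with the largest bound, and members of a list that have a bound. Genes outside the rule are marked where they appear.

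The error given with a log2 ratio combines the software's spot errors of both arrays and had a median of 0.20. The SD over repeated spots was 0.063 for the control and 0.058 for CCL22, from 282 and 287 probes with 10 spots each, or 0.086 for a ratio. Both leave out the spread between cultures, labellings and hybridisations. The number of arrays limits the precision.

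Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, cyclic loess, removal of trends with probe GC content or position on the array, no filter on background, a filter on mean signal, the authors' table, the median of a gene's probes, thresholds of 1.5-fold and 3-fold, 50 bins and unmatched random lists. A percentile over probes above background on both arrays and scaling on the spike-in spots were added after seeing the data. The calculation was tested on simulated data made from the control array's signals, with only the noise of repeated spots added. There were 200 changed genes among 15621 measured, some of them planted below 2-fold. Of those planted at 4-fold, 100% passed 2-fold in either direction, and no unchanged gene did. A list shifted by -0.60 was recovered at -0.60. This checks the arithmetic only, because the spread between cultures, labellings and hybridisations was not simulated. Python 3.11 with numpy, pandas, scipy and statsmodels was used, with limma in R for normexp, quantile normalization and cyclic loess.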

Results

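One control culture and one culture given 50 ng/mL CCL22 were compared, each on a single array, to screen for genes whose expression CCL22 affects. CCL22 is a chemokine whose classical receptor is CCR4, and KYSE410 is an established line of human esophageal squamous cell carcinoma. How long CCL22 was given is not stated in the sources used here. The treatment field of both samples instead names 10 uM defactinib, a focal adhesion kinase inhibitor, for 4 and 24 hours, while titles and study design name only CCL22. The groups below follow the titles. With 1 array per group there is no replicate check on any difference, and each value describes this pair of arrays.

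On the control array 28384 probes (48.8%) were well above background, and on the CCL22 array 30216 (51.9%). Of 10 spike-in RNAs, 8 were in range on both arrays, with 35 spots each. Their log2 ratio had a median of -0.12 after scaling and ran from -0.20 to 0.01. Across 15296 genes measured on both arrays, the signals correlated with r = 0.957, across genes and not across samples.

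For 37 probes of 32 genes, the deposited processed signal differed from the value that the same file's other columns give, and these probes were left out. They include all probes of CDH1, CDH2, TWIST1 and MMP9 that could be measured. Of the 31 that were well above background on both arrays, 28 were at least 2-fold higher on the CCL22 array and 1 at least 2-fold lower as deposited. Recomputed, 4 of the 31 were at least 2-fold higher and 10 at least 2-fold lower, and 21 log2 ratios changed sign. CDH1, the epithelial cadherin, had a deposited log2 ratio of -3.31 over 10 spots and a recomputed one of 0.02. The probes of CDH2, the neural cadherin, went from 3.03 and 2.77 as deposited to -1.46 and -1.65. Those of TWIST1, a transcription factor of mesenchymal transition, went from 2.14 at both to -0.47 and -0.48. MMP9 went from 2.42 to -0.61, and a MYC probe with 10 spots from 1.23 to -0.57. MMP3 went from 3.03 to below background on both arrays. CA9, a hypoxia-induced carbonic anhydrase, stayed high, at a CCL22 signal of 3379 as deposited and 938 recomputed, with a recomputed control signal of 4.18, not well above background. These genes were chosen after their values were seen. Below, the deposited values at these probes enter only where a result is given as deposited.

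**Figure D1:**
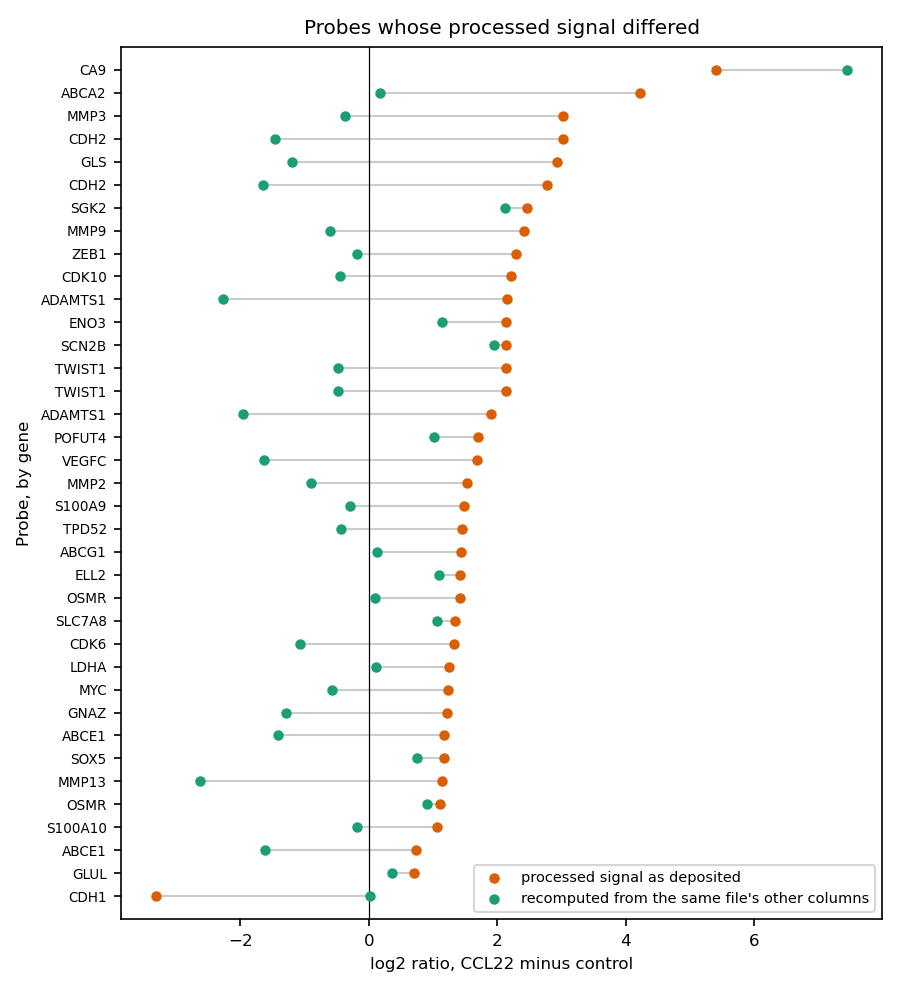
Log2 ratio (CCL22 minus control, horizontal axis) of the 37 left-out probes, 1 row per probe, with the deposited processed signal in orange and the value recomputed from the same file's other columns in green. The 6 probes not well above background on both arrays are included. The CDH1 probe moved from -3.31 to 0.02, and 21 ratios changed sign among the 31 probes well above background on both arrays, CDH1 included.

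The CCL22 array differed widely from the control. Of the 15296 genes, 1556 (10.2%) were at least 2-fold higher and 1902 (12.4%) at least 2-fold lower. ANGPTL4, a secreted regulator of lipoprotein lipase, had the largest ratio, with a log2 ratio of 6.56 ± 0.21 (94.4-fold; probe on chromosome 19, 8439197 to 8439256). NDRG1, a stress-responsive gene, followed at 5.80 ± 0.20 (55.8-fold; chromosome 8, 134249719 to 134249778). CXCL8, the neutrophil chemokine interleukin-8, was lowest at -4.72 ± 0.22 (26.4-fold lower; chromosome 4, 74609265 to 74609324). TNFRSF12A, the receptor of the cytokine TWEAK, stood at -4.01 ± 0.20 (chromosome 16, 3072180 to 3072239).

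The other genes with the highest ratios were SCN4B at 5.79, PGF at 5.03, MIR210HG at 5.02, RCOR2 at 5.00, LDHD at 4.76, DAPL1 at 4.66, NUPR1 at 4.58, BTBD16 at 4.54, GPR15LG at 4.53 and FZD10-AS1 at 4.41. The other genes with the lowest ratios were MYEOV at -3.86, CCN1 at -3.52, VWA5B2 at -3.51, CXCL1 at -3.42, FOSL1 at -3.31, DUSP6 at -3.30, DKK1 at -3.25, LIF at -3.01, BMP6 at -2.85 and LTB at -2.79. The sizes of genes dim on either array depended on background correction. With normexp the log2 ratio was 5.61 for ANGPTL4, 4.73 for SCN4B, 3.41 for MIR210HG, 3.34 for LDHD, 3.45 for BTBD16, 3.10 for FZD10-AS1 and -3.58 for CXCL8. Among genes seen above background on the CCL22 array only, COXFA4L2 was at least 29.9-fold higher, CYS1 at least 18.8-fold, SCIRT at least 16.9-fold, CPAMD8 at least 16.6-fold and C1QTNF6 at least 15.9-fold. On the control array only, LAX1 was at least 40.2-fold higher, LPA at least 35.3-fold, DACT3-AS1 at least 23.0-fold, RGL3 at least 21.4-fold and SPESP1 at least 20.8-fold. In all, 1062 genes were above background on the CCL22 array only, 398 of them with a bound of 2-fold or more, and 313 on the control array only, 159 with such a bound.

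The balance of higher against lower genes depended on the scaling, on the threshold and on the signal of the genes. The median log2 ratio of all genes was -0.25 and the interquartile range -0.69 to 0.27. Higher genes were 45.0% of those past 2-fold. Counted relative to the median gene, 2100 were higher and 1017 lower (67.4% higher). The split was 2151 and 974 (68.8% higher) with the percentile taken over probes above background on both arrays, 2089 and 880 (70.4%) after cyclic loess, 1805 and 1417 (56.0%) with spike-in scaling, 1792 and 1206 (59.8%) after quantile normalization and 1780 and 1214 (59.5%) in the authors' table. Median scaling went the other way, with 1466 and 2160 (40.4% higher). With the main scaling, higher genes were 35.5% of those past 1.5-fold and 66.7% of those past 3-fold. They were 35.2% of those past 2-fold with the filter on mean signal. Bright genes leaned lower: the median log2 ratio was 0.05 in signal decile 2, -0.51 in decile 9 and -0.41 in decile 10, the brightest. List values below are therefore relative to genes of like signal. Of 891 genes past 2-fold with several probes, 756 (84.8%) had all probes on the same side.

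**Figure D2:**
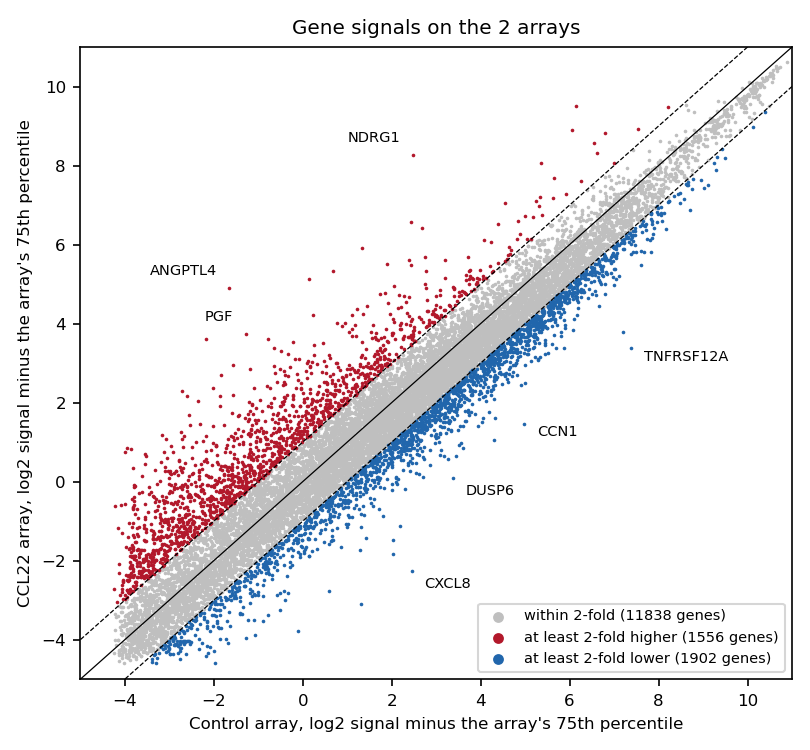
Each point is 1 of 15296 genes, with its log2 signal minus the array's 75th percentile on the control array (horizontal axis) and on the CCL22 array (vertical axis). Dashed lines mark 2-fold. The 1556 genes at least 2-fold higher on the CCL22 array are red, and the 1902 at least 2-fold lower are blue.

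CCR4 (chromosome 3, 32995840 to 32995899) and CCL22 (chromosome 16, 57399238 to 57399297) were not well above background on either array. CCL17, the other CCR4 ligand, lay near background on both arrays at a log2 ratio of -0.42 ± 0.36. PTK2, which encodes focal adhesion kinase, was at -0.07 ± 0.20, and its sign changed across the processing alternatives, which ran from -0.12 to 0.26. DGKA, a diacylglycerol kinase, was 2.19-fold higher, at 1.13 ± 0.20, and its second probe was at 0.97. One NOX4 probe, for an NADPH oxidase, was above background on the CCL22 array only, at least 6.14-fold higher, and the other was not above background on either.

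Of the list of CCL22 receptors and related ligands, CCL17 included, 8 were measured, 2 were at least 2-fold higher and none lower, and the list lay at the 60.9th percentile of matched random lists. ACKR3, an atypical chemokine receptor, was at 3.60 and CCR10 at 2.44. The median of this list was -0.04 and its mean 0.63. Of 32 focal adhesion components, 3 were higher and 5 lower past 2-fold, at the 27.8th percentile. BCAR1, an adaptor protein phosphorylated downstream of focal adhesion kinase, was at -1.33 (-0.71 as the median of its probes) and NEDD9 at 1.31 (0.44 with normexp). Integrins were at the 86.9th percentile, with ITGA5 at 1.95. The diacylglycerol kinases and NADPH oxidases were at the 96.4th percentile, with NOXA1 at 2.88 and DGKH at -1.28 (-0.81 with normexp).

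Interferon-stimulated genes were higher as a group. Of 38 measured members of the type I interferon list, 29 were at least 2-fold higher and 1 was lower. The list median was 2.43 above that of matched genes, above all 10000 random lists at the 100th percentile. IFI44L was at 3.80 ± 0.21, OAS1, which makes the activator of RNase L, at 3.78 ± 0.23, RSAD2 at 3.35 and SAMD9L at 3.34. TRIM22 was above background on the CCL22 array only, at least 7.19-fold higher. Of 28 genes of interferon gamma response and antigen presentation, 9 were higher and 2 lower past 2-fold, with a median 0.88 above matched genes (100th percentile). GBP2 was at 4.00 ± 0.31, GBP5 at 3.49 and SOCS3 at 2.14. With normexp, GBP2 was at 1.94, GBP5 at 1.99, RSAD2 at 1.38, OAS1 at 2.35 and SAMD9L at 2.04. Relative to the median gene, 32 of the type I list and 11 of the interferon gamma list were higher past 2-fold.

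The list of hypoxia and glycolysis genes was also higher as a group. Of 37 measured, 20 were at least 2-fold higher and none lower, with a median 1.61 above matched genes (100th percentile). Beside ANGPTL4 and NDRG1, the glycolytic enzymes ALDOC and ENO2 were at 3.98 and 3.76. Other glycolytic enzymes of the list stayed within 2-fold: GAPDH at -0.07, ENO1 at -0.28, TPI1 at -0.41, PGAM1 at -0.15, ALDOA at 0.17 and PGK1 at 0.60. PFKFB4 was higher, at 2.74. These genes lie outside the naming rule and were chosen after their values were seen. Of 36 ATF4 targets and genes of amino acid metabolism, 9 were higher and 1 lower past 2-fold, with a median 0.65 above matched genes (100th percentile). The stress-responsive NUPR1 was at 4.58, PCK2 at 2.91, DDIT4, an inhibitor of mTORC1 signalling, at 2.70 and ASNS, asparagine synthetase, at 2.02. DDIT4 is also in the hypoxia list. Other members stayed within 2-fold, such as TRIB3 at 0.15, SLC7A11 at -0.44 and SLC3A2 at -0.38, and the lower member was ATF5, at -1.74. TRIB3, SLC7A11, SLC3A2 and ATF5 lie outside the naming rule and were chosen after their values were seen. Of 28 genes of the unfolded protein response none passed 2-fold (88.5th percentile). Relative to the median gene, 23 hypoxia genes and 13 ATF4 targets were higher past 2-fold.

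Genes of growth and division were lower. Of 38 MYC targets and ribosome biogenesis genes, 33 were at least 2-fold lower and none higher, with a median 1.23 below matched genes, written as -1.23 (0th percentile). SRM, spermidine synthase, was at -2.50 ± 0.20, RRP9 at -2.47, RRS1 at -2.26 and UTP20 at -2.18. Of 39 G1/S genes, 27 were lower and none higher, at -0.77 relative to matched genes (0th percentile). E2F1, a transcription factor of the G1/S transition, was at -2.46, MCM10 at -1.96 and CLSPN at -1.95. RRM2 was at -2.52 on its brightest probe, and the median of its 3 probes was 0.41. Of 41 G2/M genes, 11 were lower and none higher, at -0.38 (0.04th percentile), with PLK1 at -1.90 and CCNA2 at -1.77. Of 46 replication-dependent histones, 12 were lower, at -0.29 (0.64th percentile), with H1-5 at -1.85. Of 25 heat shock genes, 11 were lower and none higher, at -0.48 (0.04th percentile), with the chaperone HSPA8 at -2.11. These counts depend on the scaling. Relative to the median gene, 30 MYC targets and ribosome biogenesis genes, 17 G1/S genes, 5 G2/M genes, 6 histones and 9 heat shock genes were lower past 2-fold. Of 69 cytosolic ribosomal proteins 1 passed 2-fold, and their median lay 0.09 above matched genes (98.0th percentile). With unmatched random lists that percentile was 61.6, and the list left the upper range under 5 settings in all.

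The target lists of ERK, YAP/TAZ and NF-kB were lower too, while immediate early genes, p53 targets and NRF2 targets lay within the range of random lists. Of 26 immediate early genes, 5 were lower and 1 higher past 2-fold, and their median was -0.11 and their mean -0.47. Of 27 ERK feedback targets, 11 were lower and none higher past 2-fold, at -0.54 relative to matched genes (0.08th percentile). DUSP6, the phosphatase of ERK, was at -3.30 ± 0.20, EREG at -2.71 and PHLDA2 at -2.19, while SPRY4 was above background on the control array only, at least 3.33-fold higher there. Of 22 YAP/TAZ targets, 10 were lower and 1 higher, at -0.67 (0th percentile), with CCN1 at -3.52, CCN2 at -2.70 (-1.28 with normexp) and FJX1 at -2.19. Of 32 NF-kB target cytokines and inhibitors, 13 were lower and 3 higher, at -0.57 (0.01th percentile). CXCL8 and CXCL1 were among the lower members, and the chemokine CCL5 was higher, at 3.41 (2.32 with normexp). CSF2 was above background on the control array only, at least 11.7-fold higher there. Relative to the median gene, 11 ERK, 8 YAP/TAZ and 9 NF-kB targets were lower past 2-fold.

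**Figure D3:**
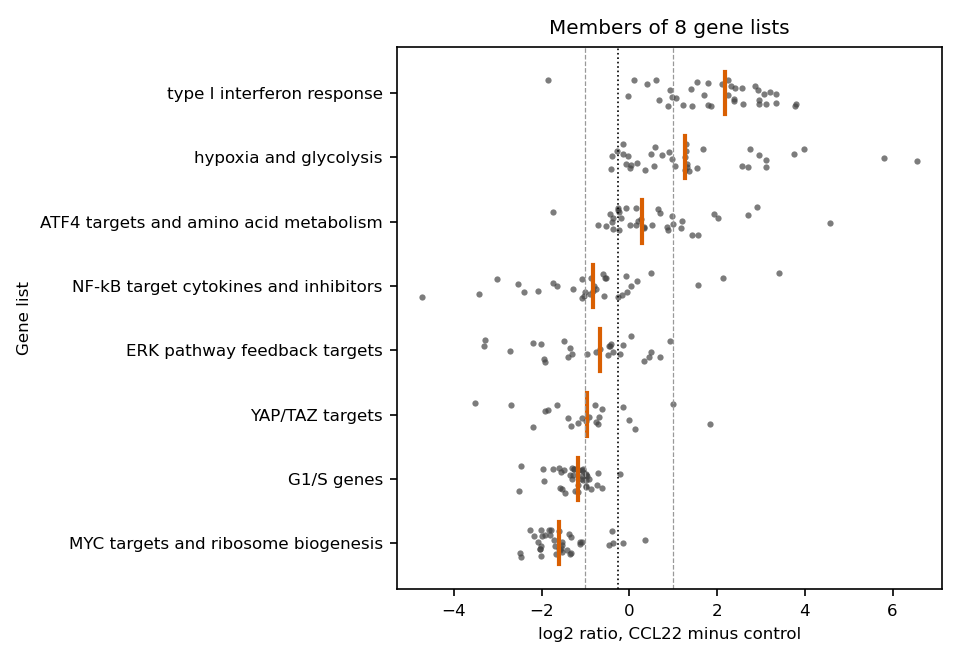
Log2 ratio (CCL22 minus control, horizontal axis) of each measured member of 8 gene lists, with the list median as an orange bar, 2-fold as dashed lines and the median of all genes (-0.25) as a dotted line. The type I interferon list had 29 of 38 members at least 2-fold higher, and the MYC and ribosome biogenesis list had 33 of 38 at least 2-fold lower.

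Squamous and mesenchymal genes gave a mixed picture. Of 21 genes of the squamous basal program, 2 were higher and 1 lower past 2-fold, and the median lay 0.75 above matched genes (100th percentile), with the basal keratin KRT15 at 3.35. Squamous differentiation genes were at the 60.3rd percentile, with 7 of 28 higher and 3 lower, KRT13 at 2.49 and SCEL at -1.79. Their median was -0.20 and their mean 0.11. Of 30 epithelial genes, 3 were higher and 5 lower (91.1st percentile), with ELF3 at 2.29 and CLDN1 at -1.65. With CDH1 the epithelial list stood at percentile 77.68 as deposited and at 97.53, just above the range of random lists, recomputed. Of 18 mesenchymal genes left, 8 were higher and 4 lower past 2-fold, with LOXL2, a collagen-crosslinking enzyme, at 4.35, TGFBI at 3.68, LOX at 2.63 and TAGLN at -2.47. With normexp LOXL2 was at 2.57 and TGFBI at 2.28. Their median lay 0.70 above matched genes (99.7th percentile). The result depended on the left-out probes and on the background filter. With 22 members it was 1.34 as deposited (100th percentile) and 0.04 recomputed (57.5th percentile), and with 30 members and no filter it was 0.19 (percentile 83.85). Matrix proteases and their inhibitors were at the 89.2nd percentile, with TIMP2 at 3.19 and MMP7 at 1.93 (0.38 with normexp). They stood at the 98.9th as deposited and at the 78.4th recomputed.

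The other lists lay within the range of random lists. They were stemness factors (percentile 97.49, with NGFR at 1.49 and ALDH1A3 at -1.79), Wnt/beta-catenin targets (96.4th, with AXIN2 at 1.90, 0.43 with normexp, and DKK1 at -3.25), immediate early genes (70.9th, JUN at -1.76), the Hedgehog pathway (80.9th, GLI1 at 1.58, 0.54 with normexp), cholesterol biosynthesis (90.6th, SREBF1 at 1.70, 0.89 as the median of its probes), NRF2 targets (77.4th, TRIM16L at -2.21) and p53 targets (58.3rd, TP53INP1 at 2.77). TGF-beta targets were at the 8.94th percentile, oxidative phosphorylation at the 81.4th with no gene past 2-fold, reference genes at the 83.8th, the epidermal growth factor family at the 61.9th and drug transport at the 23.4th. With the left-out probes, stemness factors stood at percentile 99.85 as deposited and 98.34 recomputed, both above the range, and Wnt targets at 99.44 and 97.16. Both lists lay close to the bound and passed it under other alternatives too, such as normexp. Markers of other cell types had few measured members: 7 of macrophages (5.96th percentile), 7 of T cells (66.2nd) and 5 of endothelium (88.6th). The 4 fibroblast markers measured were LUM at 2.42 (1.03 with normexp), COL1A1 at 1.29 (0.99 with normexp), DPT at -0.47 and C7 at -0.80. In all, 7 of 38 lists lay above the central 95% of random lists and 8 below it. Lists of genes drawn at random would give 1.9 outside. That number is no test here, because some lists share genes and members of a list can shift together between any cultures.

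**Figure D4:**
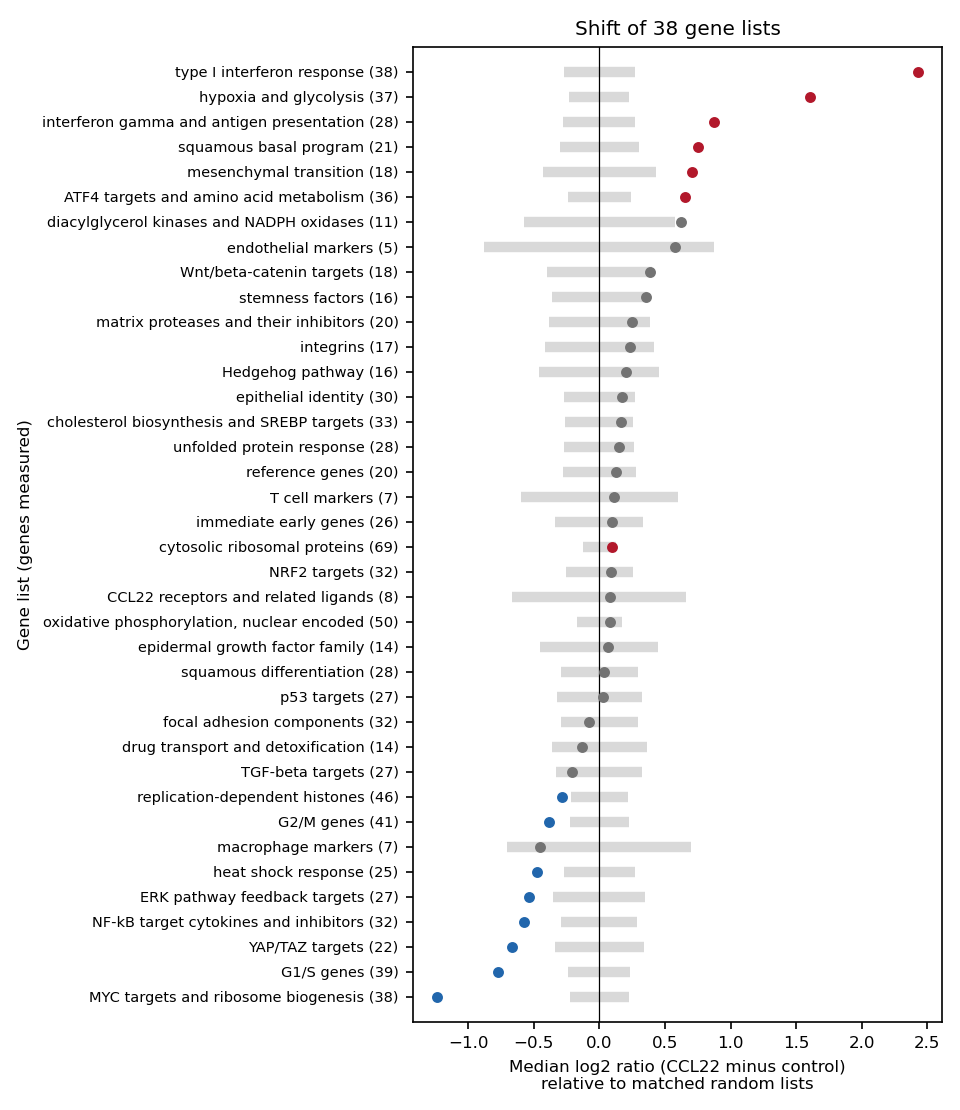
Median log2 ratio of 38 gene lists relative to matched random lists (horizontal axis), 1 row per list with its number of measured genes. Grey bars span 2 SD of random lists on each side. The 7 lists above the central 95% of random lists are red, led by type I interferon at 2.43, and the 8 below it are blue, ending with MYC and ribosome biogenesis at -1.23.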

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

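The checks on the left-out probes, on a signal-dependent difference, on the drug in the treatment field, on fibroblasts, on endotoxin and on immune cells were chosen after the results were seen.

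The processed signal of 37 probes on the CCL22 array differed from the value given by the same file's background-subtracted signal and detrending factor, against 4 probes on the control array. This stands out because the relation held within 0.001 (log2) at the other 62921 spots. No control spot was among the 55 that differed, but 60901 of the 62976 spots are gene spots, so this alone says little. The deposited value was higher at 45 spots and lower at 10, all 10 of them CDH1. At 21 spots of 12 probes the deposited value exceeded the recomputed one by a multiple of 10, within 0.1. On each array 1 spot, that of MMP3, was marked well above background although a surrogate for a dim spot had been used. These MMP3 spots were counted here as not above background. The authors' value table carries the deposited values: at the 37 probes it lay within 0.0055 of the value expected from the deposited signal, and a median of 2.34 away from that expected from the recomputed one. The files do not show how the differences arose, and no explanation was tested. For CDH1, CDH2, TWIST1, ZEB1, MYC and the matrix proteases MMP2, MMP3, MMP9 and MMP13, the deposited difference is not found in the pixel data of the same scan. Of the 32 genes, 19 had no other probe on the array.

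Among probes without a gene symbol, 1239 were well above background on the CCL22 array only and 618 on the control array only. Named genes, each counted over all its probes, leaned the same way, with 1062 on the CCL22 array only and 313 on the control array only. The lean is therefore not particular to probes without a symbol. The CCL22 array also had a lower median local background (26 against 30) and a higher median signal (19.5 against 14.4). Whether these gave the lean was not tested. The transcripts without a symbol were in no comparison. Of 6076 above background on both arrays, 582 were at least 2-fold higher and 478 at least 2-fold lower.

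The lower ribosome biogenesis, G1/S and ERK feedback lists are a first pattern to weigh. Cyclic loess removes a difference between the arrays that depends on signal. After it, the least shifted of the 3, the ERK list, lay at -0.505 relative to all genes without matching on signal (-0.420 before; SD of random lists 0.16), which argues against that difference as the whole cause. After removal of the GC trend the ERK list lay at -0.599 relative to matched genes. The treatment field names the same drug and the same times, 4 and 24 hours, for both samples, and states no difference between the arrays. The ERK targets stood at -0.539. A focal adhesion kinase inhibitor could explain this if the field were wrong for the control, or if exposure times differed between the cultures. That remains open, as do CCL22 and a difference in culture, and no array of the drug alone is at hand. These cannot be told apart, because each condition has 1 culture.

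A second pattern is the higher LOXL2, TGFBI, LOX and VIM (1.87; VIM lies outside the naming rule and was chosen after its value was seen). Fibroblasts would bring all their abundant transcripts, but 0 of COL1A2, COL3A1 and DCN were well above background on the CCL22 array, which argues against them. The signal of a DCN probe did rise, from 2.92 on the control array to 13.8 on the CCL22 array. That of the other DCN probe went from 2.63 to 2.61. The other members of the fibroblast list went both ways: LUM was at 2.42 (1.03 with normexp), COL1A1 at 1.29, DPT at -0.47 and C7 at -0.80, and 2 members were above background on the CCL22 array only. Another cell line on one of the arrays would give blocks of neighbouring genes that shift together through copy number. The SD of medians over 293 windows of 50 genes was 1.242 times its mean in 1000 shuffled orders (0.143 against 0.115, highest shuffle 0.130). That is above every shuffle but under the 1.5 set for copy number, and too close, given its spread of 0.041 over shuffles, to the lower limit set against it, so a different line could not be excluded and CCL22 stays open as well.

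The interferon response is also to be weighed. Endotoxin acting through NF-kB would raise NF-kB targets, but these lay at -0.574 relative to matched genes. Blood immune cells were not excluded: the 13 markers measured lay at -0.373 relative to matched genes, less than 2 SD of random lists (0.231 each), many were dim, and markers seen on 1 array only went both ways (MSR1 at least 2.86-fold and CSF1R at least 1.79-fold higher on the CCL22 array, where MARCO and CD247 were also seen alone, and ITGAM at least 3.51-fold and IL7R at least 1.70-fold higher on the control array). Interferon made by the cells, CCL22 itself and culture differences were not tested.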

How the results depend on the processing

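No paired analysis was possible because each group has 1 array, and leaving out an array was not possible either. Leaving out saturated spots removed nothing. Alternatives for the left-out probes, the detected-probe percentile and spike-in scaling were chosen after seeing the data. For what follows the cause was not tested. Signal over background limits the comparison: 46.9% of probes were well above background on both arrays.

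Higher genes (1556 in the report) numbered 995 with normexp, 2557 without a background filter, 855 with the filter on mean signal, 2573 at 1.5-fold and 756 at 3-fold. Lower genes (1902) numbered 1088 with normexp, 1206 after quantile normalization, 880 after cyclic loess, 1214 in the authors' table, 974 with the detected-probe percentile, 4668 at 1.5-fold and 378 at 3-fold. With the left-out probes as deposited the counts were 1579 and 1894, and recomputed 1563 and 1892.

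Of 642 list values under an alternative, 605 moved by less than the SD of random lists and 37 by more. No list outside the random range changed sign, and 6 lists within it did so by more than that SD: Hedgehog, stemness, T cells, drug transport, oxidative phosphorylation and reference genes. All 8 lists below the random range stayed below it in every setting, and 5 of the 7 above stayed above. Cytosolic ribosomal proteins left it under 5 settings and mesenchymal transition under 2. With normexp the relative median was -0.34 for ERK targets, 1.98 for type I interferon, 0.59 for interferon gamma, 1.40 for hypoxia and 0.030 for endothelial markers. With quantile normalization it was 1.43 for hypoxia, -0.63 for heat shock, 0.23 for p53 and -0.021 for TGF-beta targets, and the authors' table gave 1.41, -0.63, 0.23 and -0.023. Cyclic loess gave 1.45 for hypoxia. With the median of probes it was -0.25 for focal adhesion, 2.25 for type I interferon, -0.10 for Hedgehog, 0.17 for ribosomal proteins and -0.22 for T cells. Without a background filter it was -0.10 for stemness, 0.19 for mesenchymal genes, 0.16 for ribosomal proteins and 0.0065 for endothelial markers. With the filter on mean signal it was 0.29 for immediate early genes, -0.74 for ERK targets and 0.35 for drug transport. Against unmatched lists it was -0.91 for G1/S, -0.54 for G2/M, -0.46 for histones, -1.36 for MYC and ribosome biogenesis, 0.027 for ribosomal proteins, -0.050 for oxidative phosphorylation and -0.031 for reference genes. As deposited it was 0.57 for stemness, 1.34 for mesenchymal genes and 0.47 for proteases, and recomputed 0.036 for mesenchymal genes.

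Of 2401 values of 163 named genes, 1916 moved by less than their error, 483 by more, and 2 that were past 2-fold changed sign: FOXF1 at -0.056 with normexp against 1.06, and RRM2 at 0.41 with the median of its probes.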

Other observations

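Genes that FOXO factors induce were higher on the CCL22 array. Of 26 such genes, listed after the data were seen but before their values were read, 22 were measured. Of these, 11 were at least 2-fold higher and none was at least 2-fold lower. YPEL3 was at 3.14, KLF9 at 2.69 and KLHL24 at 2.58, while IRS2 was at -0.28 (chosen after their values were seen). In the main setting, the only one used for this list, its median was 1.12, or 1.38 above matched genes, at percentile 100. This is consistent with lower PI3K-AKT signalling, which retains FOXO factors outside the nucleus when active. It is a hypothesis, found and tested on the same pair of arrays, and these genes have other regulators.

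Depletion of glucose from the medium could raise hypoxia and ATF4 targets, and would lower TXNIP and ARRDC4, which follow glucose. The limits set beforehand were both genes at least 2-fold lower for depletion, and both at least 2-fold higher against it. TXNIP was higher, at a log2 ratio of 2.037, and ARRDC4 was at 0.70 ± 0.20. Neither was lower, but ARRDC4 fell short of the limit set against depletion, so depletion was not excluded. Low oxygen, a denser culture and CCL22 itself were not tested.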
